A study of Mus musculus with 6 samples.

How the data were processed

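Single cells from the ear skin of MC903-treated wild-type mice had been profiled with 10x Genomics 3' version 3 chemistry. The labels give 3 samples that had received vehicle and 3 that had received 6-OHDA, and the cells had been sorted as live, CD45-positive and negative for CD3e, CD5, CD11c, CD19 and NK1.1 after digestion with Liberase TL. The deposited matrices hold raw UMI counts per gene and cell, 1 matrix per sample, with no normalization. Every barcode in them has at least 500 UMIs. The submitters' notes name bcl2fastq 2.20, Cell Ranger 6.1.1 and Seurat 3.1.1, while the matrix header names version 7.1.0 of Cell Ranger. The genome build, the annotation and whether intronic reads were counted are not given in the sources used here. Genes are named as in the deposited tables, which pair 55357 mouse Ensembl identifiers with symbols, and 980 symbols shared by several identifiers were kept apart by identifier.

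Cells were read with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5. Barcodes with fewer than 200 genes detected or a mitochondrial share above 10% were left out. Scrublet scores were computed per sample. Its automatic threshold called 0.0540%, 0.112% and 0.0149% of the barcodes in 3 samples, so, as chosen after seeing these shares, the highest scores were called as doublets at a rate proportional to the sample's number of barcodes, which gave 5.11% to 7.67% per sample. Clustering used 43208 barcodes, 1981 of the 2000 most variable genes, 30 principal components, 20 neighbours and the Leiden method (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1.0, which gave 35 clusters. The 4 clusters in which at least 50% of the barcodes were called as doublets were left out, and 39626 cells remained.

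Clusters were named from marker lists written before the data were examined. Among types with at least 3 markers detected in more than 10% of the cluster's cells, that with the highest mean standardised marker level gave the name if a marker of it stood among the 10 leading genes that at least 25% of the cells had, and no other type had more markers there. This rule was written after the clusters had been looked at, and the minimum of 3 detected markers was made a condition after a cluster with fibroblast markers had scored highest for a type whose markers it lacked. Leaving out clusters made up mostly of doublet calls was also decided at that point. Of the clusters, 6 failed the rule and kept their numbers. Names carry "-like" because they rest on transcripts alone. The fixed gene lists, the comparisons, the settings and the rule for naming genes were also written before the data were examined.

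The analysed cells of a sample held 45967230 to 59414250 UMIs. UMIs were summed per class and sample where each sample had at least 20 cells. Gene counts were tested between the groups with edgeR 4.0.16 (R 4.3.3, Matrix 1.6.5) by quasi-likelihood with TMM factors and its filter on low counts, and p-values were adjusted by the Benjamini-Hochberg method within a class. Calls used an adjusted p under 0.05. DESeq2 1.42.0 was run beside it. Class shares were tested with edgeR on the numbers of cells, with the cells analysed per sample as the library size, and by an exact permutation test of the difference in means. The response of basophil-like cells was compared with the mean response of the other tested classes in 1 fit over all classes and samples with a term for each sample. Adrenergic receptor genes were compared between classes in a fit with samples as blocks.

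Of the 37 fixed lists, each with at least 5 members tested in a class was tested there with limma 3.58.1, by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. This gave 451 list and class pairs, over which p-values were adjusted. Fry tests whether the genes of a list move 1 way on balance, without comparing them with other genes. A count of members called is given over all genes tested and adjusted over the list alone.

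Genes are named by this rule. Among genes with an adjusted p under 0.05, a mean of at least 20 CPM in either group and all 6-OHDA samples on 1 side of all vehicle samples, those with the largest changes were taken, up to 12 per direction in basophil-like cells and 6 in other classes. Predicted genes, mitochondrial genes, ribosomal proteins and haemoglobins were excluded. Up to 4 members of each list and class with the smallest adjusted p under 0.05 were added, as were 9 genes for basophil-like cells, the 3 smallest p-values in classes with no call, and the adrenergic receptors. The rule names 585 gene and class pairs, and the report gives a part of them, chosen as the results state. For basophil-like cells and all cells summed, the called genes outside the rule are named too.

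The tests were tried on simulated counts with the depth, spread and sample numbers of 3 classes. At a true log2 change of 1, 73.7% of the changed genes were called with basophil-like values, 74.0% with neutrophil-like values and 65.9% with mature dendritic cell-like values.

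Settings tried beside these were DESeq2's size factors, its Wald test, no filter on low counts, replicate numbers as a block, each sample left out, at least 500 genes per cell, mitochondrial limits of 5% and 20%, doublet calls kept, Leiden resolutions of 0.5 and 2.0, equal numbers of cells per sample, and genes left out whose CPM in a class is under 10% of that in their highest class, since free RNA was not subtracted. For shares they were TMM factors on class counts and the largest class left out. Figures were drawn with matplotlib 3.10.9.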

Results

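The data were counts of single-cell transcripts from mouse ear skin. All mice had received MC903, a vitamin D analogue that causes a dermatitis resembling atopic disease. In 3 samples the mice had also received vehicle, and in 3 samples 6-OHDA, a toxin that destroys nerve endings making catecholamines and so removes sympathetic nerves. Live CD45-positive cells without CD3e, CD5, CD11c, CD19 or NK1.1 at their surface had been sorted from the digested skin. Vehicle samples 1 to 3 held 7668, 7562 and 6543 barcodes with 56627361, 57454708 and 51034290 UMIs, and 6-OHDA samples 1 to 3 held 9556, 6622 and 7057 barcodes with 68795583, 58793425 and 62890299 UMIs. After filtering, 39626 cells were analysed, between 5746 and 8238 per sample. The median mitochondrial share per barcode was 1.03%, 0.893% and 1.11% in the vehicle samples and 1.43%, 1.58% and 1.24% in the 6-OHDA samples. The ribosomal RNA gene Rn18s-rs5 took 0.966%, 0.939% and 1.95% of the UMIs in the vehicle samples and 2.17%, 1.64% and 1.52% in the 6-OHDA samples.

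The labels do not say whether the samples came from separate mice, so the p-values below measure only the spread between these samples. Changes are log2 ratios of 6-OHDA over vehicle with their standard errors, from 3 samples per group. Levels are mean normalised counts (CPM, scaled to the same library size). Samples are called vehicle 1 to 3 and 6-OHDA 1 to 3, and a value "without" a sample comes from a fit to the other 5. Of 572 called gene and class pairs that the naming rule or its stated exceptions took, 255 passed in each of the 6 fits that left out 1 sample, and the genes given below were chosen mainly from these after the values were seen, so they are steadier than the calls as a whole. Unless a sample or setting is named beside it, a gene described below as risen or fallen in a class passed in each fit that left out 1 sample and under each other setting in which it was tested. Free RNA was not subtracted. A fit without genes prone to it left out those with a level under 10% of that in their highest class: 157 of 585 named pairs stood under this limit and had no value there, and of the other 428, 427 kept direction and side of the threshold. Genes under the limit are marked as such in the account of each class, with the class where each was highest.

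Cell classes were compared first, because the study asks how losing sympathetic nerves alters skin inflammation. Neutrophil-like cells, the first granulocytes to enter inflamed tissue, fell from 24.5% ± 5.93 of the cells with vehicle to 12.1% ± 2.06 with 6-OHDA (mean ± SD, n = 3 and 3). Monocyte-like cells, recruited from blood, fell from 19.3% ± 2.71 to 8.46% ± 2.68. Mature dendritic cell-like cells, with the migration receptor gene Ccr7 among their markers, rose from 0.920% ± 0.0964 to 3.87% ± 1.93. ILC2-like cells, innate lymphocytes that make type 2 cytokines, rose from 4.15% ± 0.669 to 7.86% ± 1.15, and NK cell or ILC1-like cells rose from 0.691% ± 0.0750 to 1.82% ± 0.518. Conventional dendritic cell-like cells rose from 8.21% ± 0.579 to 13.4% ± 0.328. Cluster 10, unnamed and led by Lyz1, Retnla, Lpl, Ear2 and Fn1, rose from 3.21% ± 0.211 to 7.19% ± 1.75.

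For these classes all 3 6-OHDA samples lay on the same side of all 3 vehicle samples. The log2 ratios were -1.02 ± 0.26 for neutrophil-like cells (adjusted p = 0.0145), -1.19 ± 0.28 for monocyte-like cells (0.0138) and 2.07 ± 0.37 for mature dendritic cell-like cells (0.00984). They were 0.92 ± 0.24 for ILC2-like cells (0.0145), 1.39 ± 0.29 for NK cell or ILC1-like cells (0.010), 0.71 ± 0.20 for conventional dendritic cell-like cells (0.0226) and 1.16 ± 0.25 for cluster 10 (0.010). A further unnamed class, cluster 25, with high Cytl1 and Col8a1 and little of the CD45 gene Ptprc, had a ratio of 1.11 ± 0.35 (0.0345). The exact two-sided permutation test of each difference in mean share gave p = 0.1, the smallest that 3 against 3 samples allow. Basophil-like cells held 6.56%, 6.99% and 6.42% of the cells with vehicle and 6.03%, 2.37% and 4.98% with 6-OHDA, a ratio of -0.58 ± 0.34 that did not pass (adjusted p = 0.217, 21 classes tested). Macrophage-like (0.10 ± 0.21), mast cell-like (0.60 ± 0.26), T cell-like (0.64 ± 0.26), Langerhans cell-like (0.59 ± 0.37), keratinocyte-like (0.64 ± 0.41) and plasmacytoid dendritic cell-like cells (-0.72 ± 0.29) did not pass either, with adjusted p from 0.0762 to 0.668. Because of the sort, shares of dendritic, Langerhans, T cell-like, NK cell or ILC1-like and B or plasma cell-like classes describe what passed the gate.

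Calls changed with a sample left out. Without vehicle 2 the adjusted p rose to 0.0810 for neutrophil-like cells (-0.82 ± 0.29) and ILC2-like cells (0.80 ± 0.29), and without 6-OHDA 3 it was 0.0561 for neutrophil-like cells (-1.02 ± 0.36). The call for conventional dendritic cell-like cells was lost without vehicle 1 (0.0576), vehicle 2 (0.0835) or 6-OHDA 3 (0.0991), and that for cluster 25 without vehicle 1 (0.0605), vehicle 2 (0.0835), 6-OHDA 2 (0.0685) or 6-OHDA 3 (0.0747). Without 6-OHDA 1, basophil-like cells passed as lower (-0.86 ± 0.30, adjusted p = 0.0248), as did plasmacytoid dendritic cell-like cells (-0.79 ± 0.32, 0.0457), and Langerhans cell-like (0.92 ± 0.23, 0.00597), mast cell-like (0.82 ± 0.21, 0.00664) and B or plasma cell-like cells (1.03 ± 0.33, 0.0184) passed as higher. T cell-like cells passed without vehicle 1 (0.87 ± 0.23, 0.0435) and keratinocyte-like cells without vehicle 3 (1.22 ± 0.32, 0.0321). Shares sum to 100%: with neutrophil-like and monocyte-like cells left out, mature dendritic cell-like cells still passed (1.54), while the ratios of ILC2-like (0.42), NK cell or ILC1-like (0.88), conventional dendritic cell-like cells (0.21), cluster 10 (0.65) and cluster 25 (0.62) did not. After clustering without the 4237 genes called as changed in any class, the ratio for conventional dendritic cell-like cells was 0.52 ± 0.28 and did not pass, and 72.0% of these cells kept that name. With TMM factors on the class counts or the largest class left out, conventional dendritic cell-like (0.40 and 0.48), ILC2-like (0.62 and 0.70) and cluster 25 cells (0.80 and 0.89) did not pass.

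Basophil-like cells, which carry the IgE receptor and release IL-4, were then compared between the groups, since the study's title names basophils. The genes of the cytokines they make did not pass: Il4 was 0.18 ± 0.15 (1162 to 1316 CPM), Il13 was 0.13 ± 0.13 (558 to 613 CPM) and Il6 was 0.44 ± 0.17 (2731 to 3698 CPM), with adjusted p of 0.678, 0.731 and 0.293. The protease gene Mcpt8 (-0.56 ± 0.17, adjusted p = 0.19), the histamine-forming enzyme gene Hdc (0.13 ± 0.13) and the IgE receptor gene Fcer1a (-0.08 ± 0.14) did not pass, nor did the cAMP-induced genes Nr4a1 (0.55 ± 0.16) and Crem (0.12 ± 0.14). Mlh1, a DNA mismatch repair gene, was higher (1.73 ± 0.26, 17.3 to 61.4 CPM, adjusted p = 0.00428), as were Cldn1, of tight junctions (1.33 ± 0.20, 24.8 to 62.3 CPM), Krt16, a keratin (1.42 ± 0.24, 16.5 to 41.5 CPM), and Cpne7 (1.78 ± 0.31). Lower were Thbs1, of the matrix protein thrombospondin (-1.11 ± 0.18, 102 to 46.1 CPM), the immediate early gene Fos (-0.92 ± 0.14, 354 to 187 CPM), the actin regulators Tmsb10 (-0.72 ± 0.13) and Pfn1 (-0.70 ± 0.14), Myl12b (-0.70 ± 0.14) and Prdx5 (-0.75 ± 0.14). Krt16, Cldn1, Thbs1 and Fos stood under 10% of their level in keratinocyte-like, Langerhans cell-like, neutrophil-like and mast cell-like cells. The mitochondrial ribosomal RNA gene mt-Rnr1 (1.00 ± 0.15) was higher and the predicted gene Gm12840 (-0.89 ± 0.15) lower; both fall outside the rule for naming genes and were chosen after their values were seen.

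These were the 12 genes called in basophil-like cells, 5 higher and 7 lower of 6913 tested by edgeR; 807 had an unadjusted p under 0.05 and DESeq2's Wald test called 55, 7 of them shared. The count was 3 without vehicle 2, 76 without vehicle 3, 5 without 6-OHDA 2 and 3 without 6-OHDA 3. Mlh1 passed in each fit that left out 1 sample. The other named genes missed the threshold without certain samples, given here with adjusted p: Cldn1 without 6-OHDA 3 (0.0641); Fos without 6-OHDA 2 (0.051) or 6-OHDA 3 (0.0641); Thbs1 without vehicle 2 (0.0623) or 6-OHDA 3 (0.0641); Cpne7 without vehicle 2 (0.0881), 6-OHDA 2 (0.0647) or 6-OHDA 3 (0.0716); and Krt16 without vehicle 1 (0.0656), vehicle 2 (0.0844), 6-OHDA 1 (0.118) or 6-OHDA 3 (0.0641). The same held for mt-Rnr1 without vehicle 2 (0.0623) and Gm12840 without vehicle 1 (0.0831), vehicle 2 (0.0623) or 6-OHDA 2 (0.112). Tmsb10 missed it without vehicle 1 (0.087), vehicle 2 (0.0844), 6-OHDA 1 (0.0523), 6-OHDA 2 (0.112) or 6-OHDA 3 (0.0641), Prdx5 without vehicle 1 (0.0786), vehicle 2 (0.213), 6-OHDA 1 (0.0802), 6-OHDA 2 (0.158) or 6-OHDA 3 (0.0641), Pfn1 without vehicle 1 (0.0868), vehicle 2 (0.213), 6-OHDA 1 (0.0919), 6-OHDA 2 (0.113) or 6-OHDA 3 (0.0793) and Myl12b without vehicle 1 (0.162), vehicle 2 (0.189), 6-OHDA 1 (0.144), 6-OHDA 2 (0.112) or 6-OHDA 3 (0.0716). With equal numbers of cells per sample 2 genes were called, and neither Mlh1 (1.79) nor the other named genes passed except mt-Rnr1 and Gm12840. With doublet calls kept 28 were called, while Mlh1 (1.46), Fos (-0.20) and Thbs1 (-0.75) did not pass. The median mitochondrial share of basophil-like cells was 0.654%, 0.611% and 0.721% with vehicle and 0.936%, 0.965% and 0.779% with 6-OHDA.

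Of 30 fixed gene lists tested in basophil-like cells, 6 were called as higher and 2 as lower. That of type 2 cytokines and receptors was higher (11 members, median 0.18, adjusted p = 0.0108). Of its members 0 passed over all genes in edgeR and 3 were higher when adjusted over the list alone, and the adjusted p was 0.641 with an estimated correlation. The 12 mitochondrially encoded genes were called as higher with a median of 0.26, 0 members passing over all genes and 1 adjusted over the list alone (adjusted p = 0.668 with an estimated correlation). The keratinocyte marker list was called as higher too (6 members, median 0.67, 0 members over all genes and 2 adjusted over the list alone; adjusted p = 0.668 with an estimated correlation). Markers of mast cells (median 1.21, 5 members), inflammatory cytokines and chemokines (0.23) and ILC2 effectors (0.18) were called as higher as well, and oxidative phosphorylation genes (-0.16) and cytosolic ribosomal proteins (-0.17) as lower, each with 0 members passing over all genes in edgeR. Adjusted over the list alone, 1, 2 and 2 members were higher and 0, 1 and 0 lower in the first 3 and 0 either way in the others. With an estimated correlation the adjusted p of these was 0.651, 0.668, 0.668, 0.752 and 0.830. Mast cell markers lost their call without 6-OHDA 3 (0.205). Inflammatory cytokines lost theirs without vehicle 3 (0.580, with 1 member higher and 2 lower over all genes) or 6-OHDA 2 (0.217). ILC2 effectors lost theirs without vehicle 1 (0.0600), vehicle 2 (0.0946) or 6-OHDA 2 (0.426). The call of oxidative phosphorylation was lost without vehicle 1 (0.114) or 6-OHDA 1 (0.111) and that of ribosomal proteins without vehicle 1 (0.130) or 6-OHDA 1 (0.622). Type 2 cytokines lost theirs without 6-OHDA 2 (0.0602), mitochondrially encoded genes without vehicle 3 (0.0511), and keratinocyte markers without vehicle 2 (0.0752) or 6-OHDA 1 (0.210).

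Whether basophil-like cells responded in another way than the 15 other tested classes was tested gene by gene. Mlh1 rose more in basophil-like cells (difference 1.63 ± 0.31, adjusted p = 0.00498), and so did Cldn1 (1.36 ± 0.27, 0.00893). The test called 12 of 15366 genes, 2 higher and 10 lower, with 954 at an unadjusted p under 0.05. Without vehicle 2, 6-OHDA 2 or 6-OHDA 3 it called 0, 5 or 4, and no filter on low counts or DESeq2's size factors gave 40 or 51. Mlh1 missed the threshold without vehicle 2 (0.219), vehicle 3 (0.150) or 6-OHDA 2 (0.0556), and Cldn1 without vehicle 1 (0.139), vehicle 2 (0.219), vehicle 3 (0.286) or 6-OHDA 3 (0.112).

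**Figure D1:**
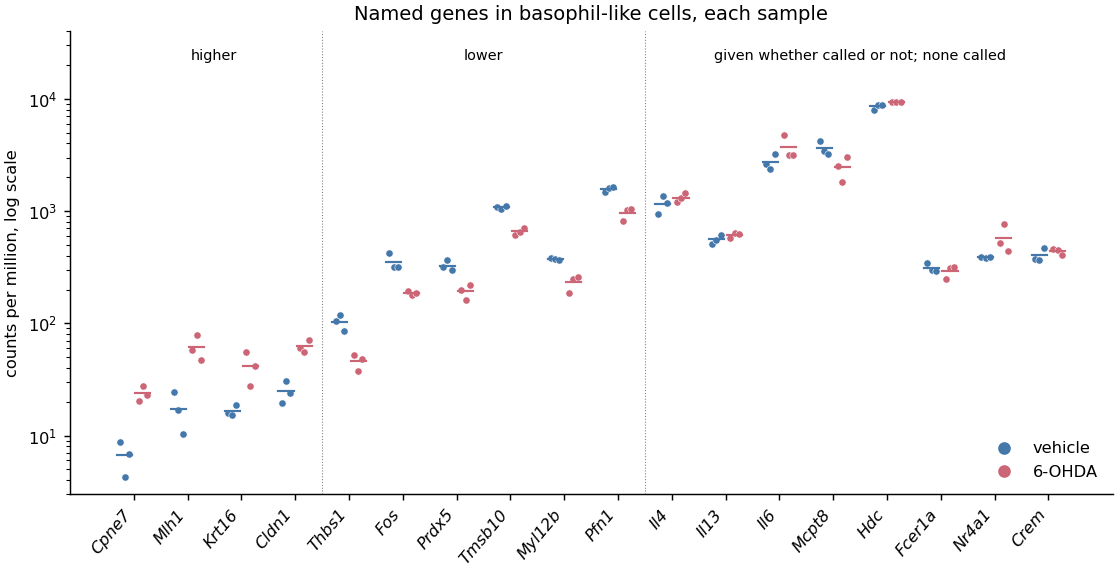
Level in CPM on a log axis of the named genes in basophil-like cells, with a point per sample for 3 vehicle and 3 6-OHDA samples and a line at each group's mean. Mlh1 rose from 17.3 to 61.4 CPM and Fos fell from 354 to 187 CPM, while Il4 and Il13 overlapped between the groups.

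Because sympathetic nerves release noradrenaline, transcripts of its receptors were compared between classes over all 6 samples. Adrb2, the beta-2 adrenergic receptor gene, stood at 125 ± 15.8 CPM in keratinocyte-like cells (mean ± SD, n = 6), 105 ± 32.4 in mast cell-like cells, 71.5 ± 10.4 in neutrophil-like cells, 57.2 ± 19.9 in T cell-like cells and 43.1 ± 3.95 in macrophage-like cells. In ILC2-like cells it stood at 25.5 ± 6.48 CPM. Basophil-like cells had 1.74 ± 1.498 CPM of Adrb2, from 18 UMIs in 9548500, which was 2.82 ± 0.29 lower on the log2 scale than the mean of the other classes (adjusted p = 4.89e-15). That p-value rests on a spread estimated over all classes and samples together, not on basophil-like cells alone. Mature dendritic cell-like cells (1.08 ± 1.36 CPM) and Langerhans cell-like cells (0.789 ± 0.486 CPM) were at a similar level, and free RNA from other cells was not subtracted. Adra1a, of the alpha-1A receptor, was most abundant in Langerhans cell-like (7.45 ± 2.43 CPM) and mast cell-like cells (4.44 ± 2.03 CPM), and Adrb1, of the beta-1 receptor, in T cell-like cells (15.4 ± 7.71 CPM).

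No adrenergic receptor gene passed for a 6-OHDA effect in any class where it was tested by edgeR. The closest were Adrb2 in cluster 10 (0.51 ± 0.18, adjusted p = 0.0865) and in ILC2-like cells (0.46 ± 0.20, 0.117). In the fit of basophil-like cells alone Adrb2 had too few UMIs to be tested. In the fit over all classes its change there was -0.89, a difference of -0.70 ± 0.88 from the mean of the other classes that did not pass (adjusted p = 1), so with 18 UMIs in all a change of this size was not detectable at this depth.

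The number of genes that changed differed widely between classes. ILC2-like cells had 1815 of 10168 genes called, 713 higher and 1102 lower, and conventional dendritic cell-like cells 1614 of 11557. Basophil-like cells had 12, and keratinocyte-like, NK cell or ILC1-like and cluster 19 cells had 0. Classes differ in cell number and depth, and differences between these counts were not tested.

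**Figure D2:**
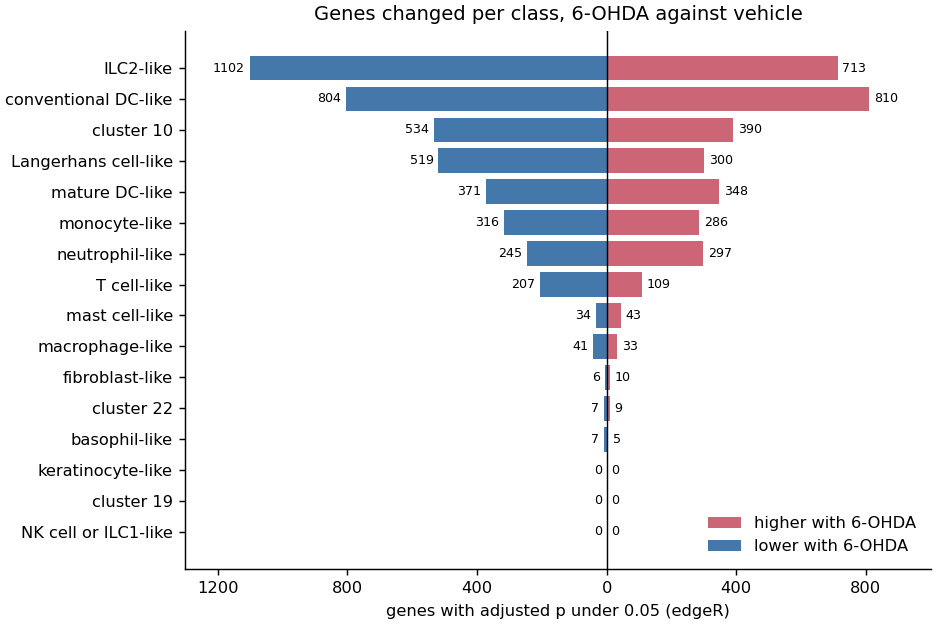
Number of genes called as higher and as lower with 6-OHDA in each class at an adjusted p under 0.05, from 3 against 3 samples. The counts run from 0 in keratinocyte-like cells to 1815 in ILC2-like cells.

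In ILC2-like cells, Il13, the type 2 cytokine gene, fell from 466 to 209 CPM (-1.16 ± 0.21, adjusted p = 0.00351, lower in 3 of 3 6-OHDA samples). Zbtb16, of the transcription factor PLZF, rose from 3.98 to 17.6 CPM (2.14 ± 0.32) and the chemokine gene Ccl22 from 4.12 to 18.3 CPM (2.10 ± 0.32). Fdps, of the mevalonate pathway (-2.10 ± 0.27), and the costimulatory ligand gene Cd70 (-1.72 ± 0.24) fell. Ramp1, a part of the receptor for the neuropeptide CGRP, fell (-0.61 ± 0.13) and Vipr2, a receptor gene for the neuropeptide VIP, rose (1.71 ± 0.39). The keratin gene Krt16 rose (1.51 ± 0.24). Under 10% of their highest level were Ccl22 (mature dendritic cell-like cells), Krt16 (keratinocyte-like) and Zbtb16 (T cell-like). Ccl22 stood at 4307 CPM with vehicle and 3762 CPM with 6-OHDA in mature dendritic cell-like cells, whose share of the cells rose from 0.920% to 3.87%. Il13 missed the threshold in cluster 13 of the class alone (adjusted p = 0.243) and without the dividing cluster 27 (0.0724).

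Cell cycle genes were lower in ILC2-like cells: 30 of 35 tested members fell over all genes and 32 adjusted over the list alone, with a median of -1.08 (adjusted p = 0.641 with an estimated correlation), including Tyms, of thymidine synthesis (-1.76 ± 0.26), Cdk1 (-1.24 ± 0.20) and Mcm2, of the replication helicase (-1.29 ± 0.21). Of 37 oxidative phosphorylation genes 29 fell, 33 adjusted over the list alone, with a median of -0.60 (adjusted p = 0.651 with an estimated correlation); Atp5g1, of ATP synthase, was -1.08 ± 0.14 (240.4 to 114 CPM) and Cox5a, of cytochrome oxidase, -0.97 ± 0.13 (374 to 192 CPM). Glucocorticoid response genes were called as higher, with a median of 0.51 and 8 of 16 members risen and 1 fallen, 10 and 1 adjusted over the list alone (adjusted p = 0.61 with an estimated correlation), among the risen Klf9 (0.77 ± 0.15) and Tsc22d3 (0.64 ± 0.13). Without vehicle 1, 4 rose. Without vehicle 1, vehicle 2, 6-OHDA 1 or 6-OHDA 2, 0 fell, and without vehicle 3, 2 fell. In cluster 15 alone Klf9 (0.29) and Tsc22d3 (0.28) did not pass. Immediate early genes, which tissue digestion also induces, were called as higher (median 0.23, 6 of 22 higher and 1 lower, 6 and 1 adjusted over the list alone; adjusted p = 0.651 with an estimated correlation), with 2 higher without vehicle 1, 1 without vehicle 2 and 4 without 6-OHDA 3. The class's cluster 27, led by cell cycle genes, held 11.5% to 12.7% of ILC2-like cells with vehicle and 4.14% to 7.72% with 6-OHDA. The class's median mitochondrial share was 1.55%, 1.44% and 1.72% with vehicle and 2.18%, 2.24% and 1.90% with 6-OHDA, and median UMIs per cell were 6785, 7143 and 6231 against 3918, 5009 and 5553. Keratinocyte markers had a median of 0.72, with 2 of 9 higher and 3 adjusted over the list alone (adjusted p = 0.668 with an estimated correlation), a call lost without vehicle 2 (0.0693), vehicle 3 (0.0608) or 6-OHDA 1 (0.178). The count of 1815 genes was 908 without vehicle 1, 918 without vehicle 2 and 1107 without 6-OHDA 2.

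Conventional dendritic cell-like cells had less Ly6c2, an antigen of inflammatory monocytes (-2.85 ± 0.19, 39.95 to 5.46 CPM, adjusted p = 7.22e-07). The chemokine gene Ccl5 (1.87 ± 0.16) and the scavenger receptor gene Cd163 (1.44 ± 0.16) rose. Ly6c2 and Ccl5 stood under 10% of their level in monocyte-like and NK cell or ILC1-like cells. Glucocorticoid response genes were called as higher (10 of 18 members risen and 1 fallen, 12 and 1 adjusted over the list alone, median 0.53; adjusted p = 0.61 with an estimated correlation), with Fkbp5, a cochaperone of the glucocorticoid receptor (1.28 ± 0.18); without vehicle 1, 6 rose. NF-kB target genes (8 of 20 risen, 14 adjusted over the list alone, median 0.36; adjusted p = 0.641 with an estimated correlation) included the feedback inhibitor gene Tnfaip3 (0.87 ± 0.10). Of 22 immediate early genes, which tissue digestion also induces, 10 rose, 17 adjusted over the list alone (median 0.42; adjusted p = 0.641 with an estimated correlation); without vehicle 1 or 2, 6 or 4 rose.

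Oxidative phosphorylation genes were lower in the same class (16 of 37 fallen, 25 adjusted over the list alone, median -0.35; adjusted p = 0.668 with an estimated correlation). Without vehicle 1, vehicle 2, 6-OHDA 1 or 6-OHDA 2 the number fallen was 7, 7, 9 or 7, and without vehicle 3 it was 25. Markers of monocytes were called as lower, with a median of -0.90 (adjusted p = 0.61 with an estimated correlation). Of 11 members 5 fell and 1 rose, 5 and 1 adjusted over the list alone. Without vehicle 2, vehicle 3, 6-OHDA 1 or 6-OHDA 3, 0 rose. Plac8 (-1.21 ± 0.14), under 10% of its level in monocyte-like cells, was among the genes that fell in the class. Markers of neutrophils were called as lower (2 of 11 fallen and 1 risen, 2 and 1 adjusted over the list alone, median -0.66; adjusted p = 0.668 with an estimated correlation), but not without vehicle 2 (0.114). The class's median mitochondrial share was 1.04%, 0.967% and 1.13% with vehicle and 1.38%, 1.45% and 1.16% with 6-OHDA. The class had 1614 genes called, 810 higher and 804 lower, and 830 without vehicle 1, 661 without vehicle 2 and 843 without 6-OHDA 2.

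In mature dendritic cell-like cells the inflammatory cytokine gene Il1b fell from 2289.6 to 836 CPM (-1.45 ± 0.18, adjusted p = 3.02e-05). Krt16 (1.75 ± 0.36) rose. Of 11 genes of MHC class II presentation 5 fell, 6 adjusted over the list alone (median -0.64; adjusted p = 0.668 with an estimated correlation), among them Cd74, the invariant chain (-1.11 ± 0.19), and H2-Ab1 (-0.97 ± 0.19); without vehicle 2, 6-OHDA 1 or 6-OHDA 2, 2, 3 or 2 fell. Il1b was under 10% of its level in basophil-like cells, H2-Ab1 in Langerhans cell-like and Krt16 in keratinocyte-like cells. The median mitochondrial share was 1.15%, 1.07% and 1.09% with vehicle and 1.34%, 1.54% and 1.26% with 6-OHDA. In this class 719 genes were called, 348 higher and 371 lower, and 318 without vehicle 2, 462 without 6-OHDA 1, 311 without 6-OHDA 2 and 421 without 6-OHDA 3.

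Langerhans cell-like cells, resident in the epidermis, had higher Abcg1, a cholesterol exporter (1.54 ± 0.14, 34.4 to 99.8 CPM, adjusted p = 3.01e-06) and Icam1 (0.81 ± 0.12). The protease inhibitor gene Timp1 (-1.61 ± 0.19), under 10% of its level in fibroblast-like cells, fell. Of 27 cell cycle genes 10 fell, 13 adjusted over the list alone (median -1.22; adjusted p = 0.641 with an estimated correlation), such as the replication helicase gene Mcm7 (-2.04 ± 0.21); without vehicle 2 or 6-OHDA 2 the number was 5 or 4, and without 6-OHDA 1 it was 21. Heat shock genes were called as lower (5 of 16, 8 adjusted over the list alone, median -0.37; adjusted p = 0.668 with an estimated correlation), with 3 lower without vehicle 1, 1 without vehicle 2 and 2 without 6-OHDA 1 or 6-OHDA 2. Markers of macrophages were called as higher (2 of 9 higher and 1 lower, 5 and 1 adjusted over the list alone, median 0.27; adjusted p = 0.668 with an estimated correlation). That call was lost without vehicle 3 (0.414), where 1 was higher and 2 lower; 1 was higher without vehicle 2 or 6-OHDA 3, and 4 without 6-OHDA 1 or 6-OHDA 2. In all 819 genes were called, 300 higher and 519 lower; the count was 443 without vehicle 1, 238 without vehicle 2 and 263 without 6-OHDA 2.

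Neutrophil-like cells had more Retnlg, of a resistin-like protein of mature neutrophils (1.94 ± 0.23, 3273 to 12581 CPM, adjusted p = 0.00214), and Pik3ip1, an inhibitor of PI3 kinase (2.16 ± 0.40). Chil3, of the chitinase-like protein Ym1, was higher (6.05 ± 0.73, 6.09 to 433 CPM, adjusted p = 0.0177), but not without vehicle 1 (0.0642) or vehicle 2 (0.133), nor in clusters 1 or 4 of the class alone, and stood under 10% of its level in monocyte-like cells. The chemokine gene Cxcl2 was lower (-0.89 ± 0.18, 17304 to 9362 CPM) but did not pass without vehicle 1 (-0.75, adjusted p = 0.0523), in cluster 1 alone (-0.28) or in cluster 4 alone (-0.09). Of 24 genes of glycolysis and hypoxia 16 were lower and 1 higher, 17 and 1 adjusted over the list alone (median -0.81; adjusted p = 0.641 with an estimated correlation), with the glycolytic gene Pgam1 at -1.15 ± 0.17, which did not pass in cluster 4 alone. Without vehicle 1, vehicle 2, 6-OHDA 2 or 6-OHDA 3, 9, 5, 7 or 10 were lower. NF-kB target genes were called as lower (5 of 19, 5 adjusted over the list alone, median -0.29, adjusted p = 0.641 with an estimated correlation). Without vehicle 2, 1 was lower, and 3 without 6-OHDA 2 or 6-OHDA 3. Immediate early genes, which tissue digestion also induces, were called as lower too (3 of 22, 3 adjusted over the list alone, median -0.17; adjusted p = 0.668 with an estimated correlation). The call was lost without vehicle 1 (0.0535), vehicle 3 (0.107), 6-OHDA 2 (0.0781) or 6-OHDA 3 (0.124), and 1, 6, 1 or 1 were lower without vehicle 2, 6-OHDA 1, 6-OHDA 2 or 6-OHDA 3. Markers of macrophages had a median of -0.90, with 1 of 11 lower, and 1 higher and 1 lower adjusted over the list alone (adjusted p = 0.741 with an estimated correlation). They lost their call without vehicle 1 (0.166), vehicle 2 (0.112) or 6-OHDA 1 (0.0773), and 6 were lower without vehicle 3 and 0 without vehicle 1, 6-OHDA 1, 6-OHDA 2 or 6-OHDA 3. Markers of monocytes were called as higher (2 of 9, 2 adjusted over the list alone, median 0.04; adjusted p = 0.641 with an estimated correlation). That was lost without vehicle 2 (0.210), vehicle 3 (0.0900), 6-OHDA 1 (0.0858) or 6-OHDA 3 (0.143), and 1 was higher without vehicle 1 or vehicle 2. The class's own markers were called as higher too (2 of 12, 4 adjusted over the list alone, median 0.12; adjusted p = 0.651 with an estimated correlation), though not without vehicle 3 (0.0654), and 1 was higher without vehicle 2. The median mitochondrial share was 0.401%, 0.333% and 0.408% with vehicle and 0.538%, 0.581% and 0.417% with 6-OHDA.

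Cluster 1 held 57% to 74% of neutrophil-like cells with vehicle and 18% to 42% with 6-OHDA, cluster 4 the rest. List calls were not separated from this shift. The class had 542 genes called, 297 higher and 245 lower, and clusters 1 and 4 alone 8 and 192 (7 and 124 shared). The count of 542 was 216 without vehicle 1, 113 without vehicle 2, 831 without vehicle 3, 204 without 6-OHDA 2 and 197 without 6-OHDA 3.

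Monocyte-like cells had more Cd163, the scavenger receptor for haemoglobin complexes (3.29 ± 0.20, 3.997 to 39.99 CPM, adjusted p = 2.84e-07) and Chil3 (1.63 ± 0.21). Plac8 (-1.34 ± 0.16) fell, and Cd163 stood under 10% of its level in macrophage-like cells. Glucocorticoid response genes were higher (6 of 17 members, 10 adjusted over the list alone, median 0.40; adjusted p = 0.537 with an estimated correlation; 3 without 6-OHDA 3), with Fkbp5 at 1.30 ± 0.14 besides Cd163. Interferon response genes were lower (9 of 30, 15 adjusted over the list alone, median -0.38; adjusted p = 0.641 with an estimated correlation); without vehicle 1, 6-OHDA 2 or 6-OHDA 3 the number was 5 each.

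Of 11 genes of MHC class II presentation 5 were higher in monocyte-like cells, 7 adjusted over the list alone (median 0.62; adjusted p = 0.668 with an estimated correlation), H2-Ab1 by 1.18 ± 0.18 and H2-Aa by 1.06 ± 0.18. Without vehicle 2, 6-OHDA 2 or 6-OHDA 3 the number was 3 each. In cluster 6 of the class alone H2-Ab1 was -0.13, H2-Aa -0.31, H2-Eb1 -0.01 and Cd74 -0.78, and at the lower clustering resolution H2-Ab1 was 0.53 and did not pass. Cluster 6 held 46% to 50% of the class with vehicle and 28% to 40% with 6-OHDA. Markers of macrophages were called as higher (4 of 12 members higher and 1 lower, 6 and 2 adjusted over the list alone, median 0.32; adjusted p = 0.641 with an estimated correlation), though not without vehicle 3 (0.255), where 2 were higher and 4 lower. With vehicle 1, vehicle 2, 6-OHDA 2 or 6-OHDA 3 left out, 2 were higher, and with vehicle 1, 6-OHDA 1, 6-OHDA 2 or 6-OHDA 3 left out, 0 were lower. Markers of neutrophils were called as higher as well (1 of 11, 2 adjusted over the list alone, median 0.17; adjusted p = 0.668 with an estimated correlation), but not without vehicle 3 (0.148) or 6-OHDA 2 (0.110), and 0 were higher without vehicle 1, vehicle 2, vehicle 3 (1 lower) or 6-OHDA 1. Of 602 genes called, 286 were higher and 316 lower, and the count was 212 without vehicle 1, 242 without vehicle 2, 1292 without vehicle 3, 250 without 6-OHDA 2 and 122 without 6-OHDA 3. In clusters 5 and 6 alone it was 1039 and 247.

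In cluster 10, Mmp12, of macrophage elastase, fell from 149.6 to 31.4 CPM (-2.23 ± 0.18, adjusted p = 1.42e-05). Apoe, of lipid transport, rose from 287 to 1046 CPM (1.87 ± 0.29), Il6 from 274 to 626 CPM (1.19 ± 0.15) and Fkbp5 from 16.9 to 55.6 CPM (1.72 ± 0.19). The neutrophil markers S100a8 (-2.57 ± 0.31), S100a9 (-2.43 ± 0.23) and G0s2 (-1.72 ± 0.33) fell, 3 of 9 members of that list and 3 adjusted over the list alone (median -0.61; adjusted p = 0.651 with an estimated correlation). These 3 genes stood under 10% of their level in neutrophil-like cells, whose share fell. The median mitochondrial share was 1.39%, 1.19% and 1.44% with vehicle and 1.63%, 1.76% and 1.47% with 6-OHDA. The 924 genes called, 390 higher and 534 lower, were 261 without vehicle 1, 333 without vehicle 2, 496 without 6-OHDA 1 and 133 without 6-OHDA 2.

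Macrophage-like cells lost Ccl8, a monocyte-attracting chemokine, from 1012 to 203 CPM (-2.32 ± 0.21, adjusted p = 0.000969), and gained Lyz1, a lysozyme gene, from 231 to 611 CPM (1.40 ± 0.13). Interferon response genes were called as lower, with a median of -0.51 over 35 members, of which 1 passed over all genes and 5 adjusted over the list alone (adjusted p = 0.668 with an estimated correlation). Over all genes 3 passed without vehicle 3, 9 without 6-OHDA 1, 2 without 6-OHDA 3 and 0 without vehicle 1, vehicle 2 or 6-OHDA 2. Markers of monocytes (12 members, median -0.55) and fibroblasts (5, -1.15) were called as lower with 0 members passing over all genes, 4 and 3 lower and 1 and 0 higher adjusted over the list alone, and adjusted p of 0.641 and 0.668 with an estimated correlation. The fibroblast call was lost without vehicle 3 (0.146) or 6-OHDA 3 (0.0770). The class's own markers were called as lower (1 of 14 lower and 1 higher, 5 and 2 adjusted over the list alone, median -0.20; adjusted p = 0.668 with an estimated correlation), but not without 6-OHDA 1 (0.0757); without vehicle 2, 0 were higher and without vehicle 3, 5 lower. In all 74 genes were called, 33 higher and 41 lower; the count was 28 without vehicle 1, 17 without vehicle 2, 287 without vehicle 3 and 20 without 6-OHDA 2.

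Mast cell-like cells had less Tpsg1, a tryptase gene, from 668 to 329 CPM (-1.02 ± 0.15, adjusted p = 0.000271), and more of the sodium pump gene Atp1b1 (1.70 ± 0.24) and Krt16 (1.44 ± 0.24), under 10% of its level in keratinocyte-like cells. Calca, which encodes the neuropeptide CGRP, was higher (1.35 ± 0.20, 80.5 to 206 CPM), though at 1.67 it did not pass with equal numbers of cells. Il13 was lower (-0.77 ± 0.15, 897 to 524 CPM) but not without vehicle 1 (0.0579) or 6-OHDA 2 (0.104). Keratinocyte markers were called as higher (2 of 5, 3 adjusted over the list alone, median 0.87, adjusted p = 0.641 with an estimated correlation). Without vehicle 1, 6-OHDA 1 or 6-OHDA 2, 1 rose. Markers of macrophages were called as lower (6 members, median -0.55, 0 either way; adjusted p = 0.668 with an estimated correlation), but not without vehicle 1 (0.0908) or vehicle 2 (0.636). Of 77 genes called, 43 higher and 34 lower, the number was 22 without vehicle 1, 173 without vehicle 3, 9 without 6-OHDA 2 and 39 without 6-OHDA 3.

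T cell-like cells, which passed the gate despite the CD3e exclusion, had less Areg, of the epithelial growth factor amphiregulin, from 324 to 90.7 CPM (-1.82 ± 0.20, adjusted p = 1.89e-06). Il17a was lower, from 403 to 119.9 CPM (-1.75 ± 0.22), though at -1.78 it did not pass with equal numbers of cells, while Nabp1 rose (1.56 ± 0.20). Cell cycle genes were called as lower (5 of 24, 13 adjusted over the list alone, median -0.90; adjusted p = 0.641 with an estimated correlation). Members passing numbered 13 without vehicle 1, 1 without vehicle 2, 3 without 6-OHDA 1 and 0 without 6-OHDA 2. Heat shock genes were called as lower (3 of 14, 5 adjusted over the list alone, median -0.45; adjusted p = 0.641 with an estimated correlation) and immediate early genes, which tissue digestion also induces, as higher (4 of 21, 6 adjusted over the list alone, median 0.34; adjusted p = 0.668 with an estimated correlation). Without vehicle 2, 6-OHDA 1 or 6-OHDA 2, 1, 1 or 0 heat shock genes were lower, and without vehicle 2 or 6-OHDA 2 0 immediate early genes were higher. Markers of T cells were called as lower (9 members, median -0.28, 0 over all genes in edgeR and 2 adjusted over the list alone; adjusted p = 0.741 with an estimated correlation), but not without vehicle 1 (0.210) or 6-OHDA 1 (0.174). The median mitochondrial share was 1.56%, 1.498% and 1.53% with vehicle and 1.99%, 2.33% and 1.96% with 6-OHDA, and median UMIs per cell were 5852, 6029 and 6006 against 4294.5, 4959.5 and 5346. Of 316 genes called, 109 higher and 207 lower, the number was 186 without vehicle 1, 37 without vehicle 2, 82 without 6-OHDA 1 and 41 without 6-OHDA 2.

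Fibroblast-like cells had more Galnt15, an O-glycosylation enzyme (2.98 ± 0.24, 70.5 to 557 CPM, adjusted p = 0.000116). The macrophage lysozyme gene Lyz2, under 10% of its level in monocyte-like cells, was lower (-2.28 ± 0.27) but at -0.39 did not pass with doublet calls kept, nor at the lower clustering resolution (-1.84). Markers of monocytes were called as lower (1 of 7, 1 adjusted over the list alone, median -0.60; adjusted p = 0.641 with an estimated correlation), with 0 passing without vehicle 2. Those of neutrophils (5 members, -1.76) and the class's own (10, -0.25) were called as lower with 0 passing over all genes, 2 each adjusted over the list alone and 1 and 0 higher (adjusted p of 0.668 and 0.752 with an estimated correlation). The first call was lost without vehicle 2 (0.0664) or 6-OHDA 3 (0.0634), the other without vehicle 2 (0.148), vehicle 3 (0.272), 6-OHDA 1 (0.298) or 6-OHDA 2 (0.0969). In this class 16 genes were called, 10 higher and 6 lower, 6 without vehicle 2 and 10 without 6-OHDA 2. Cluster 22, led by cell cycle genes, had more Bahcc1 (2.35 ± 0.29) and Fkbp5 (1.19 ± 0.18) and less of the interferon-gamma-induced chemokine gene Cxcl9 (-3.37 ± 0.43). It too had 16 genes called, 9 higher and 7 lower, with 6 without vehicle 1, 40 without vehicle 3, 5 without 6-OHDA 2 and 29 without 6-OHDA 3.

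In NK cell or ILC1-like cells no gene passed in edgeR: 364 had an unadjusted p under 0.05 and DESeq2's Wald test called 1. The IL-7 receptor gene Il7r was among the smallest p-values (1.02 ± 0.20, adjusted p = 0.106); without vehicle 2 or vehicle 3, 4 or 10 genes passed. In keratinocyte-like cells 0 of 13027 genes passed, 1682 had an unadjusted p under 0.05 and DESeq2's Wald test called 137. Without vehicle 3, 6-OHDA 1 or 6-OHDA 2, 1, 22 or 2 genes passed. Cluster 19, with a median of 810 UMIs per cell, had 0 genes called, 90 at an unadjusted p under 0.05 and 0 by DESeq2's Wald test; without 6-OHDA 1, 6 passed.

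Summed over all cells, a comparison that mixes changes in composition with changes in cells, 4 of 18270 genes passed. Gimap3, of a GTPase of lymphocytes, was higher (1.43 ± 0.11, 9.66 to 26.0 CPM, adjusted p = 0.0169), and Mgst1, a glutathione transferase gene (-0.83 ± 0.07), was lower. Gm9733 (-2.09 ± 0.16), a predicted gene, and AI839979 (-0.99 ± 0.09) were lower too, and were chosen after their values were seen. Gimap3 missed the threshold without vehicle 1 (0.229), vehicle 2 (0.0675), 6-OHDA 2 (0.0958) or 6-OHDA 3 (0.172), Mgst1 without vehicle 1 (0.229), vehicle 2 (0.127), 6-OHDA 1 (0.0561), 6-OHDA 2 (0.147) or 6-OHDA 3 (0.174), AI839979 without vehicle 1 (0.229), vehicle 2 (0.201), 6-OHDA 1 (0.0561), 6-OHDA 2 (0.147) or 6-OHDA 3 (0.174), and Gm9733 without vehicle 1 (0.229), vehicle 2 (0.068) or 6-OHDA 3 (0.172). The count was 0 without vehicle 1, vehicle 2 or 6-OHDA 3, 1 without 6-OHDA 2, 18 without 6-OHDA 1 and 2687 without vehicle 3.

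Across classes, 132 of 451 list and class pairs were called by camera with a preset correlation, 0 with an estimated correlation, and up to 150 in other splits of the same samples. Fry called 1, glucocorticoid response genes in ILC2-like cells (adjusted p = 0.0236). Oxidative phosphorylation genes were called as lower in 14 of 16 classes, from a median of -0.60 in ILC2-like and -0.57 in fibroblast-like cells to -0.15 in mature dendritic cell-like cells, and not in neutrophil-like cells (0.02) or cluster 19 (-0.04). Of these calls, basophil-like cells (-0.16) lost theirs as given above, mast cell-like cells (-0.16) without vehicle 1 (0.0571) or vehicle 2 (0.668) and mature dendritic cell-like cells without vehicle 1 (0.0645). Glucocorticoid response genes were called as higher in 10 of 16 classes, with the highest medians in conventional dendritic cell-like (0.53), ILC2-like (0.51) and monocyte-like cells (0.40). The call was lost in neutrophil-like cells (0.27) without vehicle 3 (0.104), and in keratinocyte-like cells (0.23) without 6-OHDA 1 (0.0913). In T cell-like cells (0.39) it was lost without vehicle 2 (0.0732), vehicle 3 (0.0654), 6-OHDA 1 (0.0731) or 6-OHDA 2 (0.0861).

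NF-kB target genes were called as higher in 6 of 16 classes, with medians of 0.36 in conventional dendritic cell-like cells, 0.31 in cluster 22 and cluster 10, 0.26 in Langerhans cell-like, 0.25 in monocyte-like and 0.19 in macrophage-like cells. They were called as lower in neutrophil-like cells (-0.29), a difference between classes that was not tested. The call in monocyte-like cells was lost without vehicle 3 (0.0563) or 6-OHDA 2 (0.167). Keratinocyte markers were called as higher in 8 of the 14 classes where they were tested. Medians not given above were 0.66 in conventional dendritic cell-like, 0.61 in monocyte-like and cluster 22, 0.50 in macrophage-like cells and 0.39 in cluster 10. Without 6-OHDA 1 the call was lost in monocyte-like cells (0.207). Conventional dendritic cell-like (0.111 and 0.0540) and macrophage-like cells (0.242 and 0.0561) and cluster 10 (0.253 and 0.147) lost it without 6-OHDA 1 or vehicle 2.

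Dissociation and immediate early genes, a list written for changes made by tissue digestion, were called in the same direction as NF-kB target genes in conventional dendritic cell-like, macrophage-like, monocyte-like and neutrophil-like cells and cluster 10. They were called as higher in 7 of 16 classes, with medians of 0.42 in conventional dendritic cell-like, 0.34 in T cell-like, 0.31 in cluster 10, 0.25 in macrophage-like, 0.24 in mature dendritic cell-like, 0.23 in ILC2-like and 0.16 in monocyte-like cells, and as lower in neutrophil-like cells (-0.17), with adjusted p from 0.641 to 0.752 with an estimated correlation. The call was lost in cluster 10 without vehicle 1 (0.127), in mature dendritic cell-like cells without vehicle 2 (0.379) or 6-OHDA 1 (0.118), and in monocyte-like cells without vehicle 1 (0.0822), vehicle 2 (0.112), 6-OHDA 1 (0.101) or 6-OHDA 2 (0.0857). In neutrophil-like cells it was lost as given above.

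cAMP and CREB response genes, which signals through beta-adrenergic receptors induce, were called as higher in 8 of 16 classes. The medians were 0.41 in T cell-like, 0.33 in mature dendritic cell-like, 0.32 in ILC2-like, 0.22 in conventional dendritic cell-like, 0.21 in Langerhans cell-like, 0.20 in macrophage-like cells and cluster 10 and 0.15 in monocyte-like cells. In basophil-like cells the list did not pass (0.21, adjusted p = 0.115). The list shares 6 genes with that of dissociation and immediate early genes. Its call was lost in Langerhans cell-like cells without vehicle 1 (0.105), 6-OHDA 1 (0.0858) or 6-OHDA 3 (0.0954), and in mature dendritic cell-like cells without vehicle 2 (0.157). In cluster 10 it was lost without vehicle 1 (0.346), vehicle 2 (0.0601) or 6-OHDA 1 (0.226), in macrophage-like cells without vehicle 1 (0.222), vehicle 2 (0.197) or 6-OHDA 1 (0.225), and in monocyte-like cells without vehicle 1 (0.104), vehicle 2 (0.113) or 6-OHDA 1 (0.251). For the classes called, the adjusted p lay between 0.651 and 0.752 with an estimated correlation.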

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

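The response to 6-OHDA differed between basophil-like cells and the mean of the 15 other tested classes for 12 genes, which singled them out: a difference between groups in 1 edgeR fit. Single-class tests had enough counts in 7 of the 15 for Mlh1 and Sox4, 9 for Il18r1 and 10 for Abtb1 and Cldn1. The test was planned, and the molecule counts and the class with most UMIs were looked up after the result was seen.

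Mlh1, of mismatch repair, rose by 1.64 in basophil-like cells and had a mean change of 0.01 in the others, a difference of 1.63 ± 0.31 (adjusted p = 0.00498). Its UMIs in basophil-like cells were 101 of 5777900 with vehicle and 219 of 3770500 with 6-OHDA, a ratio of 3.32 (95% counting interval 2.61 to 4.25). Cldn1, of tight junctions, had a difference of 1.36 ± 0.27 (0.00893). It had 140 UMIs there with vehicle and 242 with 6-OHDA, a ratio of 2.65 (2.14 to 3.29). Langerhans cell-like cells held most of its UMIs (18782). Counting intervals leave out the spread between samples.

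For the other genes the response of basophil-like cells lay below that of the others. Ssbp2 (-0.80 ± 0.15, adjusted p = 0.00498), Abtb1 (-1.27 ± 0.25, 0.00808), Cox7a2l (-0.61 ± 0.12, 0.00808), Ulk1 (-0.99 ± 0.21, 0.0195), 2410006H16Rik (-0.71 ± 0.16, 0.0235) and the IL-18 receptor gene Il18r1 (-1.01 ± 0.23, 0.0383) had means above 0 in the other classes, from 0.33 for Cox7a2l to 0.75 for Il18r1. The elongation factor gene Eef1a1 (-0.39 ± 0.09, 0.0235), Lpgat1 (-0.63 ± 0.13, 0.00945) and the chaperone gene Hsp90aa1 (-0.60 ± 0.14, 0.0393) had means between -0.07 and 0.09 there against -0.42, -0.54 and -0.67 in basophil-like cells in the same fit. The transcription factor gene Sox4 (-4.07 ± 0.92, 0.0393) had 34 UMIs in basophil-like cells with vehicle and 2 with 6-OHDA, a ratio of 0.0901 (0.0105 to 0.352).

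Calls changed with a sample left out: 0, 5 and 4 genes passed without vehicle 2, 6-OHDA 2 and 6-OHDA 3 (edgeR; 954 had an unadjusted p under 0.05 with all samples). Sox4 did not pass without vehicle 2 (0.636), 6-OHDA 1 (0.343), 6-OHDA 2 (0.0865) or 6-OHDA 3 (0.0615). Of the 12 genes, 10 passed with no filter on low counts and 12 with DESeq2's size factors. The splits of the samples are too few to set a share under 0.05: the real split gave 12 genes and the highest of the other splits 0, with 1 of 9 splits as large, the real one and 8 drawn at random from the others. No technical or biological explanation was tested for these genes.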

How the results depend on the processing

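Settings that concern single clusters, classes left out of the share of cells other than the largest, clustering without changed genes, and samples left out for lists and receptors were chosen after seeing the data. Except where fewer genes, cells or samples tested account for it, the cause of a change given here was not tested.

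The shares of neutrophil-like, monocyte-like, mature dendritic cell-like, ILC2-like, NK cell or ILC1-like cells and cluster 10 kept their direction under each setting. Monocyte-like (-1.45 to -0.99 with a sample left out) and mature dendritic cell-like cells (1.58 to 2.31) kept their call under each setting too. Genes called in ILC2-like and conventional dendritic cell-like cells stayed within 1.5 times their count under DESeq2's size factors, the Wald test, no filter, the block, the cell filters, resolution 2.0 and equal cells, but not with certain samples left out.

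With 1 sample left out, genes called ran from 908 to 2013 in ILC2-like, 661 to 1896 in conventional dendritic cell-like, 133 to 1314 in cluster 10, 238 to 1006 in Langerhans cell-like, 311 to 696 in mature dendritic cell-like, 122 to 1292 in monocyte-like, 113 to 831 in neutrophil-like, 37 to 455 in T cell-like, 9 to 173 in mast cell-like, 17 to 287 in macrophage-like, 3 to 76 in basophil-like, 5 to 40 in cluster 22, 6 to 20 in fibroblast-like, 0 to 10 in NK cell or ILC1-like, 0 to 22 in keratinocyte-like and 0 to 6 in cluster 19 cells, and 0 to 2687 in all cells summed. The basophil response test gave 0 to 16, lists 116 to 160 and receptors 13 to 18. Log2 ratios of shares ran from -1.17 to -0.82 for neutrophil-like, 0.65 to 0.76 for conventional dendritic cell-like, 0.80 to 1.03 for ILC2-like, 0.78 to 1.42 for cluster 25, -0.86 to -0.27 for basophil-like, 0.20 to 1.03 for B or plasma cell-like, 0.35 to 1.22 for keratinocyte-like, 0.21 to 0.92 for Langerhans cell-like, 0.47 to 0.82 for mast cell-like, -0.86 to -0.53 for plasmacytoid dendritic cell-like, 0.48 to 0.87 for T cell-like, -0.21 to 0.16 for fibroblast-like cells and -0.10 to 0.43 for cluster 32. Fibroblast-like cells turned positive without vehicle 3 (0.16) or 6-OHDA 1 (0.07), and cluster 32 negative without vehicle 2 (-0.10). Fcer1a in basophil-like cells, not called, turned to 0.022 without 6-OHDA 1.

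DESeq2's Wald test called 1 gene in NK cell or ILC1-like, 55 in basophil-like, 38 in cluster 22, 61 in fibroblast-like, 137 in keratinocyte-like and 229 in macrophage-like cells, and 1757 in all cells. Its size factors in edgeR gave 25 in all cells and 51 in the basophil response test. No filter on low counts gave 16 in NK cell or ILC1-like, 98 in basophil-like, 12 in cluster 19, 166 in cluster 22, 230 in fibroblast-like, 397 in keratinocyte-like, 598 in macrophage-like, 132 in mast cell-like and 1105 in monocyte-like cells, 666 in all cells and 40 in the basophil response test.

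No class had all 3 correlations of same-numbered samples over 0.1, so replicate numbers were not taken to pair samples. They were 0.06, 0.19 and -0.05 over all cells, 0.20, 0.32 and -0.01 in keratinocyte-like cells and 0.15, 0.04 and 0.18 in fibroblast-like cells, where each sample correlated best with its own number. With these numbers as a block, genes called were 4 in NK cell or ILC1-like, 587 in cluster 10, 29 in cluster 22, 176 in fibroblast-like and 12 in keratinocyte-like cells and 0 in all cells, where edgeR without the block had 3959 at an unadjusted p under 0.05, and the share of conventional dendritic cell-like cells (0.71) missed the threshold (0.0617).

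Keeping doublet calls gave 138 genes in T cell-like, 28 in basophil-like, 57 in fibroblast-like and 1 in keratinocyte-like cells and turned the share of cluster 32 to -0.22. It reversed Osm in ILC2-like (-0.10), Retnlg in Langerhans cell-like (-0.40), Chil3 in fibroblast-like (0.67) and Tnf in mature dendritic cell-like cells (-0.10), all 4 under 10% of their level in, in turn, basophil-like, neutrophil-like, monocyte-like and macrophage-like cells. A mitochondrial limit of 5% turned the share of cluster 32 to -0.046. At resolution 0.5, 60 genes were called in fibroblast-like and 188 in monocyte-like cells and 26 in all cells, the fibroblast-like share was 0.29, and Ddit4 in Langerhans cell-like cells (-0.20) and Cd209a (-0.45), Il1rn (-0.016) and C1qa (-0.35) in monocyte-like cells reversed. At that resolution the conventional dendritic name covered another population and was not compared, as decided after its values were seen. At resolution 2.0, 128 genes were called in fibroblast-like cells, their share was 0.19, and Adm in conventional dendritic cell-like (-0.18) and Isg15 in monocyte-like cells (0.13) reversed. Adm, Cd209a and C1qa stood under 10% of their level in fibroblast-like, conventional dendritic cell-like and macrophage-like cells. Equal numbers of cells, and so fewer cells, gave 69 genes in T cell-like, 2 in basophil-like, 547 in cluster 10, 4 in cluster 22, 48 in macrophage-like and 280 in mature dendritic cell-like cells, with Il4 (-0.18) and Fcer1a (0.11), not called, reversed in basophil-like cells.

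TMM factors on class counts gave share ratios of -0.87 for basophil-like and -1.02 for plasmacytoid dendritic cell-like cells, both then passing, and 0.80 for cluster 25, 0.40 for conventional dendritic cell-like and 0.62 for ILC2-like cells, which then did not pass. They reversed cluster 19 (-0.014), cluster 32 (-0.10) and macrophage-like cells (-0.21). With the largest class left out these were -0.93 for plasmacytoid dendritic cell-like cells, passing, 0.89 for cluster 25, 0.48 for conventional dendritic cell-like and 0.70 for ILC2-like cells, not passing, and -0.013 for cluster 32 and -0.13 for macrophage-like cells, reversed. With neutrophil-like and monocyte-like cells left out, cluster 10 (0.65), cluster 25 (0.62), conventional dendritic cell-like (0.21), ILC2-like (0.42) and NK cell or ILC1-like cells (0.88) did not pass, plasmacytoid dendritic cell-like cells (-1.20) passed, and cluster 19 (-0.19), cluster 32 (-0.29) and macrophage-like cells (-0.40) reversed. With the classes low in Ptprc left out, T cell-like cells passed (0.69). With clustering that left out changed genes, conventional dendritic cell-like cells did not (0.52). In each of these fits the denominator of all shares changes by construction.

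Single clusters, with fewer cells, gave 8 genes (cluster 1) and 192 (cluster 4) for neutrophil-like, 1039 (cluster 5) and 247 (cluster 6) for monocyte-like and 935 (cluster 13) and 490 (cluster 15) for ILC2-like cells. In cluster 1 Bcl2a1d (0.092) and Sod2 (0.14) reversed, in cluster 4 Bcl2a1d (0.20), Ier5 (0.0061), Nfkbia (0.23) and Hilpda (0.045), in cluster 5 Ramp1 (0.25) and in cluster 15 Ptgir (-0.17). In cluster 6 Egr1 (-0.18), Mt1 (-0.14), Cd209a (-0.50), Il1rn (-0.14), C1qa (-0.71), H2-Ab1 (-0.13), H2-Eb1 (-0.011), H2-Aa (-0.31), Cd74 (-0.78) and Ndufa4 (0.0059) reversed, of which Egr1 and Mt1 stood under 10% of their level in mast cell-like and fibroblast-like cells, and Cd209a and C1qa as above. Camera with an estimated correlation called 0 lists, where the preset correlation called 132, and fry called 1.

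Of 589 named gene and class pairs, 579 kept direction and side of the threshold with DESeq2's size factors, 500 of 534 with the Wald test, 564 with no filter, 515 with the block, 512 with doublets kept, 445 of 562 with equal cells, 427 of the 428 that could be tested with genes prone to free RNA left out, 374 of 433 at resolution 0.5 and 471 of 505 at resolution 2.0. With a sample left out the number lay between 348 of 589 without vehicle 2 and 534 without vehicle 3. At the depth of 3 classes and a true log2 change of 1, simulated counts gave 65.9% to 74.0% of the changed genes; classes without calls were not simulated.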

Other observations

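Of the tests in this part, the comparison of ILC2-like with neutrophil-like cells, the shares with both granulocyte and monocyte classes left out, the barcodes left out before clustering, and the cell cycle list in other classes were chosen after the results were seen.

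Ccl22, a chemokine gene that draws T cells with the receptor CCR4, was higher in several classes. In ILC2-like cells it rose by 2.10 ± 0.32, in monocyte-like cells it was 1.56 ± 0.28 (1.37 in their cluster 6 alone, where it did not pass) and in Langerhans cell-like cells 1.52 ± 0.22 (61.0 to 177 CPM), where it did not pass with doublet calls kept (1.41, adjusted p = 0.0794). Each stood under 10% of the level in mature dendritic cell-like cells, whose level and share are given above. Free RNA was not subtracted.

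The salivary gland gene Dcpp1 gave 15, 16982 and 6608 UMIs in the vehicle samples and 8, 15368 and 83797 in the 6-OHDA samples, and 1 barcode held up to 48009 of them. Th, of noradrenaline synthesis, gave 0 UMIs in 5 samples and 1 in 6-OHDA 2.

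Oxidative phosphorylation genes were lower in ILC2-like cells with 6-OHDA (median -0.60). The list was called as lower in 14 of 16 classes. The difference from neutrophil-like cells had a median of -0.65 over 37 genes (quartiles -0.77 and -0.41), with 35 below 0. It cannot decide on a library effect alike in all classes, as the pair was chosen after its medians were seen. Fewer cells of the dividing cluster are argued against by the median without that cluster, -0.63, with 28 genes still lower in edgeR. A shared effect of like or differing size stays open. So do the lower UMIs per cell of ILC2-like cells with 6-OHDA and a biological effect of the lost nerves.

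The shares of neutrophil-like and monocyte-like cells were lower and those of other classes higher with 6-OHDA. For mature dendritic cell-like cells, a fall of both classes that raises all others alike is argued against by their ratio of 1.54 with both classes left out, which still passed. For the other classes called as higher it cannot be told apart from a rise of their own: 0 of them passed with both classes left out in edgeR, and their ratios lay between 0.21 and 0.88. The doublet calls and the 10% mitochondrial limit are argued against by the ratio of neutrophil-like cells with all 43208 clustered barcodes counted, -0.99 ± 0.26, while the limits that left out 1800 of 45008 barcodes before clustering stay open: with those of the 6-OHDA samples all counted as neutrophil-like and those of the vehicle samples not, it was -0.48 ± 0.26. Losses in tissue digestion or sorting and a biological effect of 6-OHDA stay open and were not tested.

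Cell cycle genes were lower in ILC2-like cells with 6-OHDA (median -1.08). Fewer cells of the dividing cluster as the whole cause are argued against by a median of -0.87 over 20 members without that cluster, of which 12 were still lower and 1 higher. RNA of dividing cells outside the class stays open: of 15 other classes the list was called as lower in 6, among them Langerhans cell-like (-1.22) and T cell-like cells (-0.90), and as higher in monocyte-like cells (0.47). Fewer dividing cells within the other clusters of ILC2-like cells, as a biological response to 6-OHDA, may also account for it and stay untested.

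The 6 samples allow 10 splits into groups of 3, too few to set a share under 0.05. The real split gave as many genes as 1 of 10 splits, itself, in ILC2-like (1815 against at most 0 in another split), conventional dendritic cell-like (1614 against 0), cluster 10 (924 against 0), Langerhans cell-like (819 against 1), mature dendritic cell-like (719 against 1), monocyte-like (602 against 0), neutrophil-like (542 against 2), T cell-like (316 against 7), mast cell-like (77 against 2), macrophage-like (74 against 0), cluster 22 (16 against 1), fibroblast-like (16 against 0) and basophil-like cells (12 against 0), in all cells summed (4 against 0) and for shares (8 classes against 0). In NK cell or ILC1-like (0 against 1), keratinocyte-like (0 against 1) and cluster 19 cells (0 against 6), all 10 gave as many. For lists, 4 of the 10 splits called as many, with 132 in the real split and at most 150 in another.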
